A study of Homo sapiens with 15 samples.

How the data were processed

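Values came from 15 per-library tables and 1 series table as the authors deposited them. RNA with a RIN above 8 was made into stranded libraries and sequenced as 50 bp reads, per the submitters' processing notes. The notes name Trimmomatic 0.32, STAR 2.4, featureCounts from Subread 1.4.6p4, edgeR and RSEM, and the GRCh38 genome. The release of the gene annotation and the strand setting of the counting are not given in the sources used here. Per the labels, the expected counts of each library are estimated counts that the authors' RSEM run divided over genes. The TPM values beside them are from the same RSEM run, scaled by the authors for gene length and library size. In the series table, the counts that the authors deposited are whole numbers of reads per gene for the 6 HFF libraries. The log2 values in it are log2 fold changes of 50 kPa over 1 kPa as deposited by the authors. The p-values in it, with an FDR, are those of the authors' test of the same groups. That table was used to set its results beside those here and as an alternative set of counts; its 6 per-sample columns of scaled counts were not used here.

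Gene identifiers were matched to GENCODE release 29 for symbols, gene classes and GRCh38 locations. Of 60483 genes, 56753 were in that annotation. Genes were counted as they came, and expected counts, of which 8.5% to 14.6% per library were not whole, were rounded. Genes with low counts were removed with filterByExpr, which left 17324 genes in the fit of the 6 HFF libraries, 16085 in that of the 9 A549 libraries and 18424 in the fit of all 15. TMM factors ranged from 0.961 to 1.048 in HFF cells, from 0.943 to 1.047 in A549 cells and from 0.926 to 1.082 in the joint fit. Comparisons used robust quasi-likelihood tests in edgeR 4.0.16 with 3 residual degrees of freedom in HFF cells, 6 in A549 cells and 9 in the joint fit. The difference between cell types is the interaction, the 50 kPa over 1 kPa fold change of A549 cells less that of HFF cells. Adjusted p-values are Benjamini-Hochberg values over all genes of a comparison, and a gene is called changed at an adjusted p under 0.05. A standard error of a log2 fold change is its size over the square root of the test's F. Levels are means of CPM with TMM factors. Replicates with the same number were not treated as pairs, since the labels do not establish pairing.

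Genes were named in the text by a rule. It takes the 9 genes of the series description, the genes with the largest change each way among called genes with an average log2 CPM of at least 4 whose groups do not overlap, leaving out mitochondrial, rRNA, histone and sex-linked marker genes (8 each way for 50 kPa against 1 kPa and 4 for the other comparisons), and up to 4 called members per list with the smallest adjusted p. Genes outside it are marked as chosen after their values were seen, and some genes that the rule names are not reported here. There were 39 gene lists with 726 members, 1 of them unmatched, and lists with fewer than 4 tested members are given as counts. Lists were tested in limma 3.58.1 with camera at a preset correlation of 0.01, with camera at a correlation estimated from each list, and with fry. The test with an estimated correlation also rests on the residual degrees of freedom, 3 in HFF cells, 6 in A549 cells and 9 in the joint fit. With so few, calls are rare whatever the correlation, so a lost call is by itself no sign that the genes of a list move together. Adjusted p-values of lists are over the lists of a comparison. The comparisons, the lists, the naming rule and most alternatives were chosen before the data were examined, and the alternatives added later are named with their results.

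The alternatives were DESeq2 1.42.0, limma-voom, limma-trend on log2 of TPM plus 1, RLE factors, library totals, no filter on low counts, a mean of at least 5 CPM, a block for replicate number, only the compared groups in the fit, an adjusted p under 0.01, a 2-fold limit, and each library left out in turn. Where an HFF group was left with 1 library, that library was assumed to vary like the other groups. Work was done in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

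The steps were tested on simulated data made from these libraries with 200 genes changed. The changed genes were drawn only from those with a mean of at least 50 counts, so recovery of genes with lower counts was not tested. At a log2 fold of 0.5, 1 and 2, edgeR recovered 41.8%, 85.1% and 98.5% of the changed genes among 16963 tested for HFF 50 kPa against 1 kPa, 46.3%, 83.6% and 98.5% among 16977 for HFF TCP against 1 kPa, and 34.3%, 83.6% and 95.5% among 16959 for HFF TCP against 50 kPa. In the A549 design it recovered 53.7%, 85.1% and 98.5% among 15870 for 50 kPa against 1 kPa, 55.2%, 89.6% and 100% among 15848 for TCP against 1 kPa, and 52.2%, 83.6% and 98.5% among 15873 for TCP against 50 kPa. For the difference between cell types it recovered 16.4%, 67.2% and 90.9% among 18099 genes. False calls numbered 20, 29, 26, 13, 11, 7 and 9 in that order. In the HFF comparisons they made up a larger share of the calls than the adjusted p threshold is meant to allow. For HFF TCP against 50 kPa, 26 false calls stood beside 23, 56 and 63 recovered genes at these folds. In the data this comparison called 76 genes, and some of them may be false calls. For the A549 comparisons and the difference between cell types the excess was smaller or absent. Camera called the simulated list in each comparison and 0 others, and fry called 0 or 1 others. Each gene was given the same spread in all libraries, whereas the real libraries were uneven. Chi-square per degree of freedom between replicates was 80.2 on HFF 50 kPa and 3.64 on HFF TCP, and 5.38 to 85.4 within A549 1 kPa. The recovery and false calls thus need not hold for these libraries. Each gene was also simulated independently, so this cannot show how the list tests behave when the genes of a list move together. In the data the estimated correlation reached 0.987, for G2/M genes in HFF cells on 50 kPa against 1 kPa.

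Across protein-coding genes, length on the genome, introns included, was set against the log2 fold change. In A549 cells the Spearman correlation was 0.206 for 50 kPa against 1 kPa, 0.169 for TCP against 1 kPa and 0.075 for TCP against 50 kPa. In HFF cells it was -0.042, -0.028 and 0.028. Genes with near-identical copies, such as ribosomal proteins, histones and HSPA1A with HSPA1B, share reads at 50 bp, and their values are uncertain. Reads were not aligned again, and splice forms were not analysed here.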

Results

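RNA was sequenced from 2 kinds of human cells 20 hours after seeding on a soft hydrogel (1 kPa), a stiff hydrogel (50 kPa) or tissue culture plastic (TCP). Primary human fibroblasts (HFF) gave 2 libraries per substrate and A549 lung adenocarcinoma cells gave 3, which makes 15 libraries. Expected counts per library ranged from 42615271 to 95747370 in HFF cells and from 29243536 to 34229699 in A549 cells. Of 60483 genes, 17324 passed the filter on low counts in HFF cells and 16085 in A549 cells. The coefficient of variation between libraries of a group was 0.108 in HFF cells and 0.111 in A549 cells. Seeding differed with the substrate: 70000 HFF cells on 1 kPa against 40000 on 50 kPa and TCP, and 2000000 A549 cells on 1 kPa against 1250000 on 50 kPa. The number of A549 cells on TCP is not given in the sources used here, and except between HFF cells on 50 kPa and TCP, the effect of seeding cannot be separated from that of the substrate. TCP differs from the hydrogels in material as well as in stiffness. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples.

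The comparison of 50 kPa with 1 kPa in HFF cells addresses which genes of fibroblasts respond to a stiffer hydrogel. Of 17324 genes tested, 6612 changed at an adjusted p under 0.05, 3362 of them higher and 3250 lower on 50 kPa (edgeR quasi-likelihood test, n = 2 libraries per group). Changes of at least 2-fold were more often lower, in 1191 genes, than higher, in 491. CCN1, which encodes a secreted matrix protein and is a target of the coactivators YAP and TAZ, rose from 376.1 to 1178 CPM (log2 fold change 1.65 ± 0.07 SE, adjusted p = 7.24e-05). BMF, which encodes a pro-apoptotic BH3-only protein that binds motor complexes of the cytoskeleton, fell from 26.43 to 1.11 CPM (log2 fold change -4.58 ± 0.20, adjusted p = 5.93e-05). NF2, which encodes merlin, an upstream regulator of the Hippo pathway, rose from 44.2 to 89.18 CPM (1.01 ± 0.06, adjusted p = 0.000121). MYH9, the heavy chain of nonmuscle myosin IIA, rose by less, with a log2 fold change of 0.45 ± 0.08 (adjusted p = 0.00551). CCN2, another secreted YAP and TAZ target, had 1.05 ± 0.29 (adjusted p = 0.0335). Among the other abundant genes, EDN1 (endothelin) rose by 2.49 on the log2 scale and PMAIP1, a p53 target, by 2.05, while TNXB, which encodes the matrix protein tenascin-X, had -3.99. CCN1 (ENSG00000142871.14) lies on chromosome 1 at 85580761 to 85583962 of GRCh38, and BMF (ENSG00000104081.12) on chromosome 15 at 40087890 to 40108892.

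The count of 6612 genes depended on single libraries: it fell without either HFF 1 kPa library and rose without either HFF 50 kPa library. Each of these fits left 1 library in a group. Without 1 kPa replicate 2, MYH9 had 0.40 with an adjusted p of 0.0545. The CCN2 call was lost without any of 3 libraries: the gene had 1.29 (adjusted p = 0.0674) without 1 kPa replicate 1, 0.86 (0.144) without 1 kPa replicate 2 and 0.56 (0.145) without 50 kPa replicate 2. The authors' deposited table compares the same HFF groups from other counts of the same libraries. It lists 5890 genes with an adjusted p under 0.05, 3118 higher and 2772 lower on 50 kPa. Of the genes tested here, 5158 were called in both, all with the same sign, 1454 only here and 383 only by the authors. The log2 fold changes had a Pearson correlation of 0.787 across the genes tested here.

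Matrix and mesenchymal genes fell in HFF cells on 50 kPa. Of 28 measured genes for collagens and other matrix proteins, 20 fell, 0 rose and 8 did not pass. The fibroblast markers fell in 8 of 10 cases, and with COL3A1 at -1.89 ± 0.08 and COL1A2 at -1.16 ± 0.07 the fibrillar collagens were among them. PDGFRB and PDGFRA, receptors for platelet-derived growth factors, had -1.85 ± 0.09 and -1.45 ± 0.09. Of the 15 genes for crosslinking and collagen processing, 11 fell and 2 rose. Of the 19 matrix proteases and inhibitors 11 fell and 2 rose, with SERPINE2, an inhibitor of thrombin and plasminogen activators, at -1.70 ± 0.08. Counts adjusted over the list alone were 20 lower for the matrix proteins, 9 lower for the fibroblast markers, 11 lower for crosslinking and 11 lower for proteases. All 4 lists passed the camera test with a preset correlation (adjusted p = 3.18e-13, 6.6e-14, 0.000819 and 0.000819). With an estimated correlation they did not: adjusted p = 0.398, 0.131, 0.398 and 0.398 with an estimated correlation. The estimates were 0.737 for matrix proteins and 0.115 for crosslinking. For fibroblast markers and proteases they were -0.017 and -0.052, below the preset 0.01, so those calls were not lost to a higher correlation. The median of the matrix list, -0.74, was -0.48 without 50 kPa replicate 1.

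Genes of the cytoskeleton and of YAP and TAZ rose in the same comparison. Of 22 YAP/TAZ-TEAD targets, 13 rose, 2 fell and 7 did not pass, with a median log2 fold change of 0.61. Of 24 cytoskeletal targets of SRF and MRTF, 14 rose and 1 fell, among them TAGLN (1.38 ± 0.12), ACTB (0.83 ± 0.11) and TPM1 (0.58 ± 0.09). Adjusted over the list alone, the counts were 13 higher and 2 lower for the YAP and TAZ targets and 14 higher and 1 lower for the SRF targets. All 9 genes that the series description names changed, 8 higher and 1 lower, also when adjusted over the list alone, which is not independent evidence since the study drew on these libraries. The camera test with a preset correlation gave adjusted p = 8.05e-06 for YAP and TAZ targets, 0.000281 for SRF targets and 0.000403 for the 9 genes, against adjusted p = 0.398, 0.51 and 0.398 with an estimated correlation.

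Cell-cycle and stress genes moved as well in HFF cells on 50 kPa, though several of these lists leaned on 1 of the 50 kPa libraries. Of 30 genes of G1/S and DNA replication, 25 rose and 0 fell (29 rose when adjusted over the list alone), with TYMS at 1.34 ± 0.14 and CDT1 at 1.06 ± 0.09. Of 28 genes of G2/M and mitosis, 10 rose and 18 did not pass (6 rose when adjusted over the list alone), with CDK1 at 1.21 ± 0.15. Genes of the list for ATF4 and the unfolded protein response fell in 13 of 20 cases and rose in 1, counted over all genes and adjusted over the list alone, with ASNS at -1.47 ± 0.12 and PSAT1 at -0.91 ± 0.09. p53 targets rose in 6 of 18 cases, counted either way, with GADD45A at 1.71 ± 0.08 and FAS at 1.04 ± 0.13. NRF2 targets fell in 7 of 20 cases and rose in 1, counted either way, with ABCC3 at -1.58 ± 0.14. Adjusted p from camera with a preset correlation was 1.44e-12 for G1/S, 0.000281 for G2/M, 0.000213 for ATF4, 0.00484 for p53 and 0.00508 for NRF2. These calls were lost at adjusted p = 0.51, 0.597, 0.398, 0.597 and 0.597 with an estimated correlation. The p53 median of 0.49 was 0.06 (adjusted p = 0.456) without 50 kPa replicate 1 and 0.86 without replicate 2. The NRF2 median of -0.49 was -0.94 without replicate 1 and -0.14 (adjusted p = 0.324) without replicate 2. The G2/M median of 0.77 was 1.18 without replicate 1 and 0.26 without replicate 2, and the G1/S median of 0.85 was 0.55 without replicate 2.

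Those 2 libraries of HFF cells on 50 kPa differed from each other more than the HFF pairs on 1 kPa or TCP did. Chi-square per degree of freedom over genes was 80.2 between them, against 8.70 on 1 kPa and 3.64 on TCP. Summed over p53 targets, 50 kPa replicate 1 had 3280 CPM and replicate 2 had 1854, against 1396 and 1513 on 1 kPa. Over G2/M genes they had 3536 and 6683 CPM, against 2938 and 2908 on 1 kPa. CDKN1A, a p53 target chosen after its values were seen, had 1615 CPM in 50 kPa replicate 1 and 751 in replicate 2. CCNB1, a mitotic cyclin also chosen after its values were seen, had 123 and 235 CPM.

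The camera test with a preset correlation also called lysosome and autophagy genes (10 of 20 fell, median -0.25), genes for TGF-beta response (11 of 20 fell, 2 rose), mesenchymal and EMT markers (8 of 16 fell, 1 rose) and glycolysis (10 of 20 rose, 2 fell), each at adjusted p = 0.00299, 0.000756, 0.00469 and 0.00758, and at adjusted p = 0.398, 0.398, 0.51 and 0.398 with an estimated correlation. SLC2A1, the glucose transporter GLUT1, rose by 1.23 ± 0.07 on the log2 scale. Camera also called 8 lists whose calls ended when 1 library was left out. These were focal adhesion genes (14 of 30 rose, 4 fell; adjusted p = 0.0929 without 1 kPa replicate 2), mitochondrial mRNAs (9 of 13 fell; 0.0593 without 1 kPa replicate 1), interferon response (9 of 20 fell; 0.109 without 50 kPa replicate 2) and mesenchymal growth factors and receptors (7 of 23 rose, 10 fell; 0.184 without 50 kPa replicate 2). Wnt genes (4 of 18 rose, 6 fell) had 0.0519, 0.185 and 0.109 without 1 kPa replicate 1 or either 50 kPa library, and ribosomal proteins (11 of 30 rose, 1 fell) 0.0625 and 0.143 without 1 kPa replicate 1 or 50 kPa replicate 1. Heat shock genes (7 of 12 rose) had 0.058 and 0.0966 without 1 kPa replicate 1 or 50 kPa replicate 2, and leukocyte markers (3 of 4 fell) 0.0566 and 0.0891 without 1 kPa replicate 1 or 50 kPa replicate 1. In all, 24 of 36 lists were called with the preset correlation, 0 with the estimated one and 22 by fry, which tests whether the genes of a list move on balance one way.

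**Figure D1:**
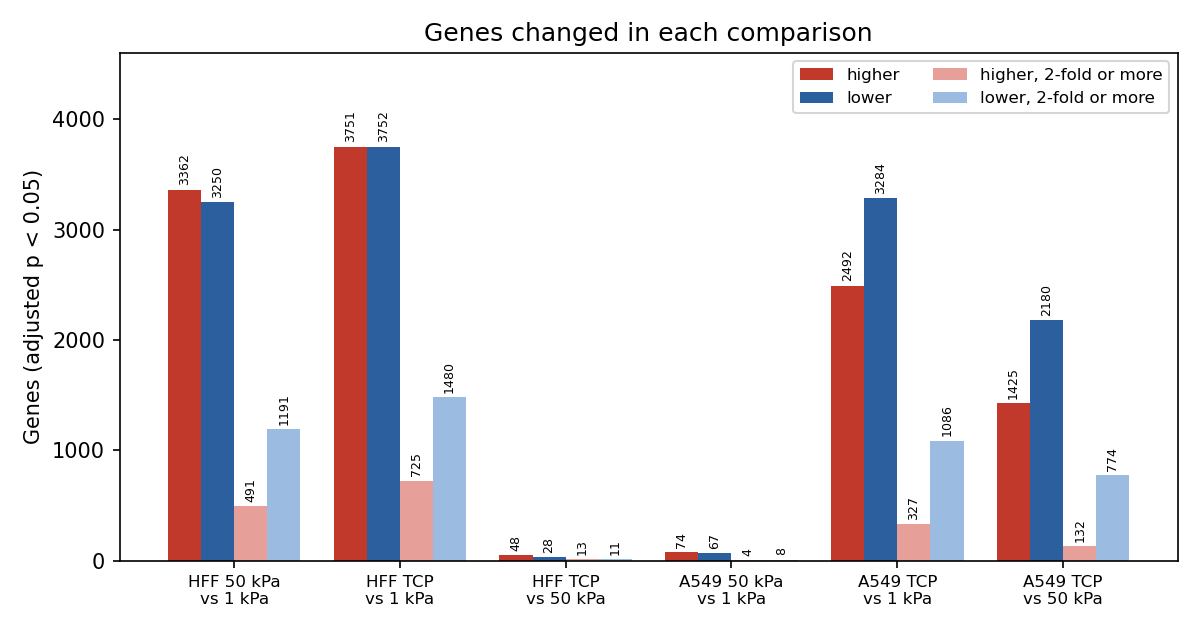
Number of genes (y axis) past an adjusted p of 0.05 in each comparison (x axis), split into higher and lower, and those changed at least 2-fold. The counts are lowest for HFF cells on TCP against 50 kPa (48 higher, 28 lower) and for A549 cells on 50 kPa against 1 kPa (74 higher, 67 lower).

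The comparison of TCP with 1 kPa in HFF cells addresses how far growth on plastic differs from growth on a soft hydrogel. Of 17324 genes, 7503 changed, 3751 higher and 3752 lower on TCP, and 2205 changed at least 2-fold (725 higher, 1480 lower; n = 2 libraries per group). BMF fell to 0.346 CPM (log2 fold change -6.28 ± 0.24, adjusted p = 1.99e-05) and CCN1 rose to 1396 CPM (1.89 ± 0.07, adjusted p = 2.01e-05). MYH9 rose by 0.94 ± 0.08 on the log2 scale (adjusted p = 0.000239) and NF2 by 1.18 ± 0.06 (adjusted p = 5.17e-05). NEFM, a neurofilament subunit, rose from 10.9 to 105.4 CPM (3.27 ± 0.09, adjusted p = 1.02e-05). HTRA3, a secreted serine protease, fell from 75.23 to 3.37 CPM (-4.48 ± 0.12, adjusted p = 1.02e-05), and COL15A1, a basement membrane collagen, had -6.03 ± 0.32 (adjusted p = 7.05e-05). The count was 3967 and 4218 without 1 kPa replicate 1 or 2, and 3937 and 3646 without TCP replicate 1 or 2. CCN2 had 1.30 ± 0.29 (adjusted p = 0.0151), and the call was lost without 1 kPa replicate 2 (1.11, adjusted p = 0.0738), without TCP replicate 1 (1.32, 0.066) and without TCP replicate 2 (1.31, 0.0717). With libraries scaled by their totals only, 39.5% of the changed genes were higher, against 50.0% with TMM factors. NEFM (ENSG00000104722.12) lies on chromosome 8 at 24913012 to 24919098.

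In the gene lists for TCP against 1 kPa, 20 of 24 SRF targets rose and 0 fell (22 rose when adjusted over the list alone), with TAGLN at 1.84 ± 0.12 and TPM1 at 1.15 ± 0.09. Mitotic genes rose in 18 of 28 cases (27 when adjusted over the list alone) and G1/S genes in 23 of 30 (27 when adjusted over the list alone). NRF2 targets fell in 13 of 20 cases (14 when adjusted over the list alone), with ABCC3 at -2.38 ± 0.14. Of the matrix proteins 17 of 28 fell and 2 rose, and of the matrix proteases 13 of 19 fell and 3 rose, counts that were the same when adjusted over the list alone, with COL3A1 at -1.65 ± 0.08 and MMP14 at -1.34 ± 0.07. Cytosolic ribosomal protein genes, whose reads are shared with many pseudogenes, rose in 24 of 30 cases (25 when adjusted over the list alone). Camera with a preset correlation gave adjusted p = 1.28e-10 for SRF targets, 6.7e-06 for G2/M, 1.75e-08 for G1/S, 2.33e-07 for NRF2, 7.99e-07 for matrix proteins, 5.88e-05 for proteases and 4.38e-05 for ribosomal proteins. Of the 22 calls 0 held with an estimated correlation, where these 7 lists had adjusted p = 0.377, 0.566, 0.496, 0.476, 0.496, 0.331 and 0.377 with an estimated correlation, while fry called 27 lists.

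The comparison of TCP with 50 kPa in HFF cells addresses whether plastic differs from the stiff hydrogel in fibroblasts. At an adjusted p under 0.05, 76 genes changed, 48 higher and 28 lower on TCP, and 2805 of 17324 had an unadjusted p under 0.05 (n = 2 libraries per group). CEMIP, a hyaluronan-degrading protein, rose from 219.1 to 688 CPM (log2 fold change 1.65 ± 0.09, adjusted p = 0.000949) and NEFM rose by 1.51 ± 0.09 (adjusted p = 0.0014). HTRA3 had -2.31 ± 0.11 (adjusted p = 0.000949), and these 3 genes stayed past the threshold whichever library was left out. SERPINB2, an inhibitor of plasminogen activators, had -1.22 ± 0.06 (adjusted p = 0.000949), and -1.23 (adjusted p = 0.0537) without TCP replicate 2. The count was 3552 without 50 kPa replicate 1 and 3292 without 50 kPa replicate 2, and 5 without TCP replicate 1 and 3 without TCP replicate 2. By DESeq2 it was 757 and by limma-voom 38. With library totals as the only scaling, 38.2% of the changed genes were higher, against 63.2% with TMM factors. HTRA3 (ENSG00000170801.8) lies on chromosome 4 at 8269765 to 8307111, and CEMIP (ENSG00000103888.14) on chromosome 15 at 80779343 to 80951776.

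Few members of any gene list passed in HFF cells on TCP against 50 kPa, so the list medians carry this comparison. Of the 24 SRF targets 1 rose over all genes and 12 rose when adjusted over the list alone, with a median of 0.30 (camera adjusted p = 1.04e-15 with the preset correlation, adjusted p = 0.295 with an estimated correlation). That gene was FHL1, at 1.05 ± 0.11 (adjusted p = 0.0281), and -0.80 ± 0.09 was found for the collagenase MMP1 (adjusted p = 0.0281). Both calls ended without TCP replicate 1 (FHL1 1.06, adjusted p = 0.324, and MMP1 -0.75, 0.461) and without TCP replicate 2 (1.05, 0.33, and -0.85, 0.33). Cholesterol genes had 0 of 24 members past the threshold over all genes and 9 higher when adjusted over the list alone (median 0.25, camera adjusted p = 4.08e-07, and adjusted p = 0.294 with an estimated correlation). The median of SRF targets was 0.47 without 50 kPa replicate 2. Lists of the cell cycle and of p53 had opposite directions with either 50 kPa library: without replicate 1 the G2/M median of 0.20 was -0.17 and the p53 median of -0.06 was 0.41, and without replicate 2 the G1/S median of -0.11 was 0.16. Camera called 24 lists, 0 of them with an estimated correlation, and fry called 6.

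The comparison of 50 kPa with 1 kPa in A549 cells puts the question of hydrogel stiffness to a carcinoma line. At an adjusted p under 0.05, 141 of 16085 genes changed, 74 higher and 67 lower on 50 kPa, with 2983 at an unadjusted p under 0.05 (n = 3 libraries per group). ASNS, which encodes asparagine synthetase, fell from 90.31 to 46.26 CPM (log2 fold change -0.96 ± 0.10, adjusted p = 0.00883), and NUPR1, a stress-induced chromatin protein, had -1.05 ± 0.15 (adjusted p = 0.0174). ANKRD1, a YAP target that binds titin in muscle, rose from 2.585 to 6.271 CPM (1.28 ± 0.19, adjusted p = 0.0175). CCN2 rose by 0.70 ± 0.10 (adjusted p = 0.0174), CCN1 by 0.57 ± 0.10 (adjusted p = 0.0421), and COL5A1, a fibrillar collagen chain, by 0.85 ± 0.14 (adjusted p = 0.029). MYH9 and BMF did not pass, with 0.66 ± 0.15 (adjusted p = 0.0771) and -0.64 ± 0.15 (adjusted p = 0.0729). ASNS (ENSG00000070669.15) lies on chromosome 7 at 97852118 to 97872542, and ANKRD1 (ENSG00000148677.6) on chromosome 10 at 90912096 to 90921276.

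Single libraries decided that count. It was 1849 without A549 1 kPa replicate 3, with all 141 genes among them, and 53 without 1 kPa replicate 1. It was 5 without 50 kPa replicate 1 and 0 without 50 kPa replicate 2 or 3 by the same edgeR test, while DESeq2 with all libraries called 869 and limma-voom 135. Fold changes moved less: without 50 kPa replicate 3, ASNS had -0.96 (adjusted p = 0.0764), NUPR1 -1.12 (0.102), ANKRD1 1.32 (0.122), CCN2 0.75 (0.102), CCN1 0.52 (0.229) and COL5A1 0.82 (0.171). Without 50 kPa replicate 2 they had -1.05 (0.0585), -1.07 (0.104), 1.09 (0.104), 0.63 (0.104), 0.55 (0.163) and 0.85 (0.135). Without 50 kPa replicate 1, ASNS stayed past the threshold, and the other 5 had adjusted p of 0.0978, 0.0579, 0.0763, 0.12 and 0.125. Without 1 kPa replicate 1, CCN1 had an adjusted p of 0.0621 and COL5A1 of 0.0549, and without 1 kPa replicate 2 CCN1 had 0.051. Without 1 kPa replicate 3, MYH9 and BMF passed, with 0.46 (adjusted p = 7.04e-07) and -0.70 (adjusted p = 0.00323). With library totals as the only scaling, 40.4% of the changed genes were higher, against 52.5% with TMM factors.

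A549 1 kPa replicate 3 stood apart from the other libraries of its group. Chi-square per degree of freedom over genes was 60.7 and 85.4 between it and the other two, against 5.38 between those and 3.57 to 8.93 within the 50 kPa and TCP groups. It had the lowest sum of YAP and TAZ targets, 1367 CPM against 2090 and 2162, and the highest sums of cytosolic ribosomal proteins, 39635 CPM against 29563 and 27784, and of mitochondrial mRNAs, 16539 CPM against 10016 and 11912.

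In the gene lists of this comparison, ATF4 and unfolded protein response genes fell in 9 of 20 cases and rose in 1 (13 lower and 4 higher when adjusted over the list alone), with PHGDH, of serine synthesis, at -0.61 ± 0.07. Of 22 YAP/TAZ-TEAD targets, 6 rose and 0 fell (8 rose when adjusted over the list alone). G1/S genes rose in 3 of 30 cases (19 when adjusted over the list alone), with E2F2 at 0.44 ± 0.08. Collagens and other matrix proteins rose in 1 of 24 cases (13 when adjusted over the list alone). The 13 mitochondrially encoded mRNAs had a median of -0.44, 1 of them past the threshold and 8 when adjusted over the list alone. Camera with the preset correlation gave adjusted p = 7.84e-11 for ATF4, 4.88e-14 for YAP and TAZ, 5.76e-12 for G1/S, 6.86e-10 for matrix proteins and 2.72e-09 for mitochondrial mRNAs. The G1/S list alone among 24 called lists held at adjusted p = 0.00605 with an estimated correlation, and the other 4 had 0.121, 0.121, 0.148 and 0.149 with it, while fry called 20. The YAP and TAZ median of 0.39 was 0.17 (adjusted p = 2.27e-13) and the mitochondrial median -0.28 (adjusted p = 2.16e-08) without 1 kPa replicate 3. The matrix median of 0.61 was 0.37 (adjusted p = 6.86e-07) without 50 kPa replicate 3. The ribosomal protein list, called with a median of -0.19 (camera adjusted p = 2.75e-05, adjusted p = 0.478 with an estimated correlation), had -0.01 (adjusted p = 0.502) without 1 kPa replicate 3. PHGDH and E2F2 stayed at -0.62 and 0.44 without 50 kPa replicate 3, with adjusted p of 0.102 and 0.177, and ended likewise without 50 kPa replicate 1 (0.0763, 0.168) or replicate 2 (0.0994, 0.125), and E2F2 without 1 kPa replicate 1 (0.0874).

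**Figure D2:**
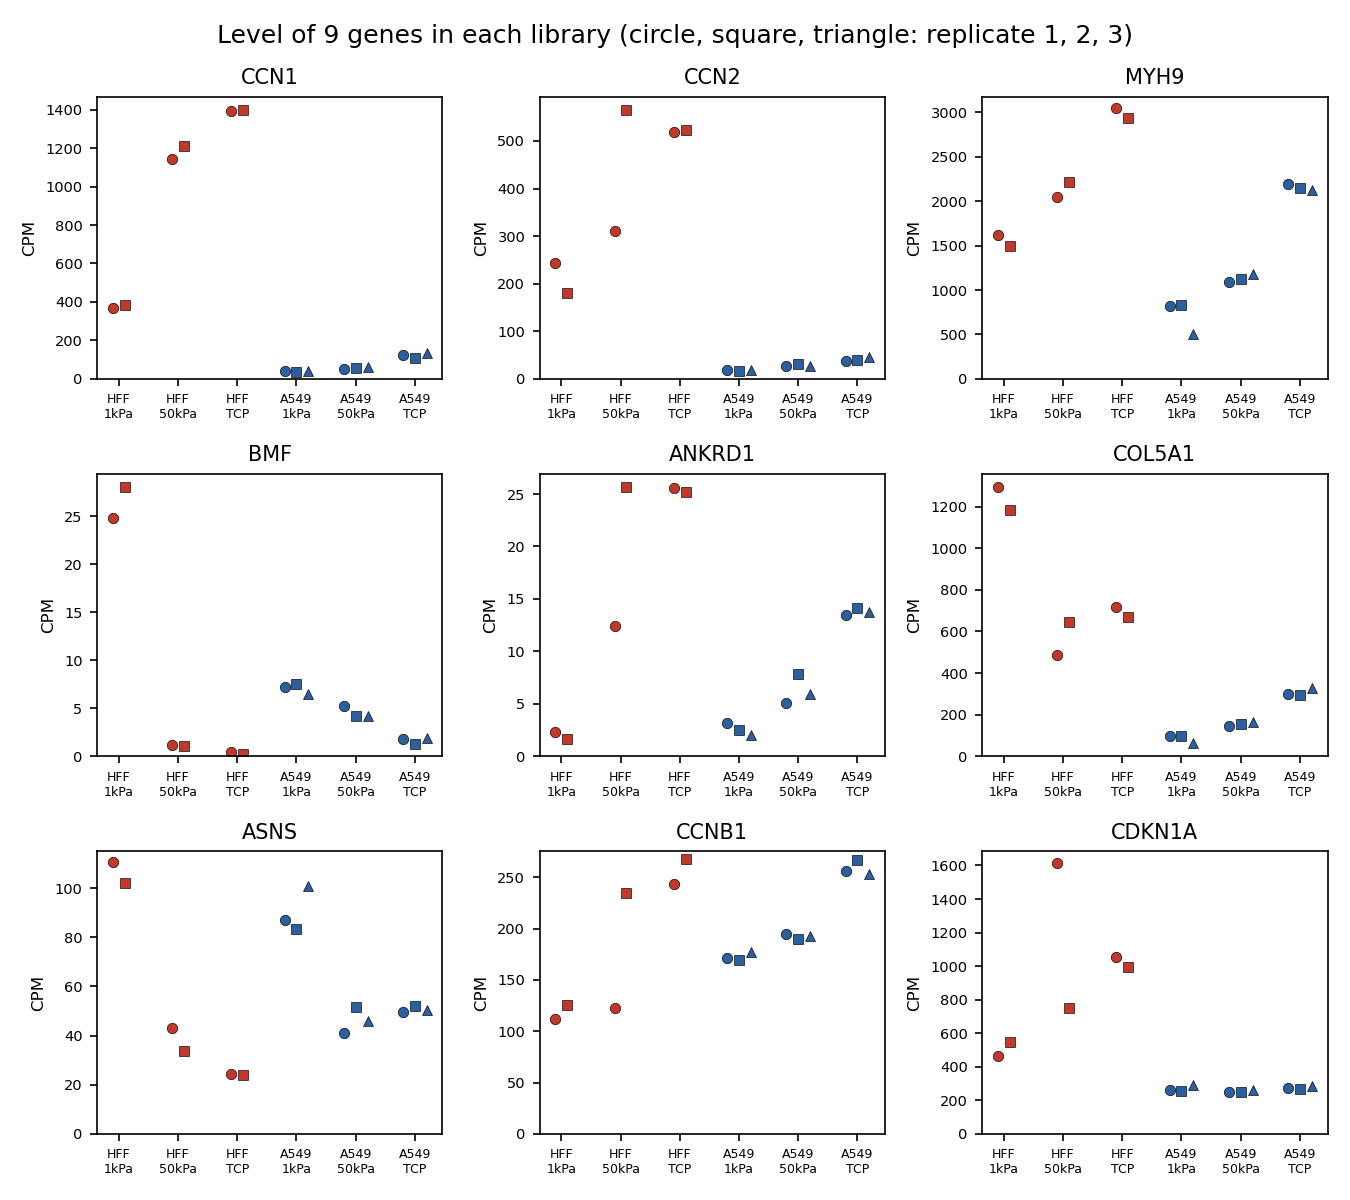
Level in CPM (y axis) of 9 genes in each library (points) of the 6 groups (x axis); red, HFF cells; blue, A549 cells. BMF fell from 26.43 to 1.11 CPM in HFF cells between 1 and 50 kPa, and the 50 kPa replicates of HFF cells lay apart in CCNB1 and CDKN1A, which were chosen after their values were seen.

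The comparison of TCP with 1 kPa in A549 cells addresses how far plastic differs from a soft hydrogel in the carcinoma line. Of 16085 genes, 5776 changed, 2492 higher and 3284 lower on TCP, and 1413 changed at least 2-fold (327 higher, 1086 lower; n = 3 libraries per group). MYH9 rose from 718.6 to 2158 CPM (log2 fold change 1.59 ± 0.16, adjusted p = 5.29e-05) and CCN1 from 37.99 to 121.9 CPM (1.68 ± 0.11, adjusted p = 3.85e-06). BMF fell from 7.058 to 1.656 CPM (-2.08 ± 0.16, adjusted p = 1.22e-05). AQP3, a water and glycerol channel, fell from 68.49 to 7.638 CPM (-3.17 ± 0.18, adjusted p = 2.11e-06), and NEAT1, the long noncoding RNA of paraspeckles, fell from 713.8 to 134 CPM (-2.41 ± 0.09, adjusted p = 1.06e-06). All 9 genes that the series description names changed, 8 higher and BMF lower. The count was 4172, 4266 and 4495 without TCP replicate 1, 2 or 3, and 4940, 5994 and 8009 without 1 kPa replicate 1, 2 or 3. Of 140 named genes that changed, 138 did so without each library in turn. Most of these were named for a small adjusted p or a large change in the same data, which favours this. With library totals as the only scaling, 22.5% of the changed genes were higher against 43.1% with TMM factors, since the median log2 fold change of all genes was -0.165 with totals and -0.041 with TMM. NEAT1 (ENSG00000245532.5) lies on chromosome 11 at 65422774 to 65445540.

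Adhesion, contractility and sterol genes rose together in A549 cells on TCP. Of 22 YAP/TAZ-TEAD targets, 20 rose and 0 fell, and of 22 SRF targets 17 rose and 2 fell, with TAGLN at 2.18 ± 0.11 and TPM1 at 1.58 ± 0.08. Of 30 focal adhesion and actomyosin genes, 25 rose and 2 fell (26 and 2 when adjusted over the list alone), with PXN, which encodes paxillin, rising from 167.1 to 359.2 CPM. Cholesterol genes rose in 19 of 24 cases and fell in 1 (20 and 1 when adjusted over the list alone), with HMGCS1 at 1.14 ± 0.09. Mitotic genes rose in 21 of 28 cases (23 when adjusted over the list alone), with PLK1 at 0.67 ± 0.05, and G1/S genes rose in 19 of 30 and fell in 1 (20 and 1 when adjusted over the list alone). NF-kB and cytokine genes rose in 10 of 17 cases and fell in 1 (12 and 1 when adjusted over the list alone), with NFKB2 at 0.94 ± 0.06. NRF2 targets fell in 13 of 20 cases, counted either way, with GCLC, of glutathione synthesis, at -0.97 ± 0.06. Within the immediate early genes FOS had -3.17 ± 0.19 while FOSL1 and JUN had 1.59 ± 0.09 and 1.64 ± 0.10. With an estimated correlation, 7 of the 22 camera calls held: SRF targets, cholesterol and the 9 genes of the series description (adjusted p = 0.018 each with an estimated correlation), G1/S (0.0207), G2/M (0.0293), and YAP and TAZ targets and focal adhesion (0.0366 each). NF-kB and NRF2 lists, with camera adjusted p = 3.08e-06 and 2.68e-06, had adjusted p = 0.131 and 0.0948 with an estimated correlation.

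The comparison of TCP with 50 kPa in A549 cells addresses whether plastic differs from the stiff hydrogel. Of 16085 genes, 3605 changed, 1425 higher and 2180 lower on TCP (n = 3 libraries per group). At 2-fold or more, 132 were higher and 774 lower. NEAT1 had -2.28 ± 0.09 (adjusted p = 1.79e-06) and MYH9 0.93 ± 0.15 (adjusted p = 0.00201). AXIN2, a feedback target of Wnt signalling, fell from 25.84 to 4.578 CPM (-2.50 ± 0.13, adjusted p = 3.91e-06), and IL11, a cytokine of TGF-beta response, rose from 20.75 to 69.25 CPM (1.74 ± 0.09, adjusted p = 3.91e-06). The count was 2221 without 50 kPa replicate 1, 2270 without 50 kPa replicate 3, 2254 without TCP replicate 1 and 2289 without TCP replicate 2. With library totals as the only scaling, 16.7% of the changed genes were higher, against 39.5% with TMM factors, and the median of all genes was -0.126 against -0.011.

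All 13 mitochondrially encoded mRNAs rose in A549 cells on TCP against 50 kPa, also when adjusted over the list alone, with a median of 1.01 and MT-ND2 rising from 747.8 to 1979 CPM (camera adjusted p = 9.7e-18, and adjusted p = 0.0872 with an estimated correlation). Mitochondrial genes took 2.46% to 2.56% of counts on TCP, 1.12% to 1.31% on 50 kPa and 1.44% to 2.25% on 1 kPa. Within these shares, mitochondrial rRNA took 0.700% to 0.750%, 0.270% to 0.316% and 0.398% to 0.583%. SRF targets rose in 16 of 22 cases and fell in 1 (17 and 2 when adjusted over the list alone), and cholesterol genes in 18 of 24 (19 when adjusted over the list alone), with INSIG1 at 0.93 ± 0.07. Wnt receptors and targets fell in 9 of 19 cases and rose in 1 (11 and 1 when adjusted over the list alone), with RNF43 at -2.19 ± 0.16. Camera gave adjusted p = 2.61e-16, 3.26e-12 and 1.22e-05 for these 3 lists, and adjusted p = 0.0305, 0.0186 and 0.0822 with an estimated correlation. The 9 genes of the series description (7 higher, 1 lower, counted either way) were the other list to hold, at adjusted p = 0.049 with an estimated correlation. Camera called 17 lists, and fry 25. Matrix protein and crosslinking lists had medians of 0.02 and 0.04, means of -0.45 and -0.06 and an upward camera test (adjusted p = 0.0287 and 0.035, and adjusted p = 0.6 and 0.295 with an estimated correlation), and the matrix median was 0.46 without 50 kPa replicate 3. These 2 calls were lost without 50 kPa replicate 1 (adjusted p = 0.124 and 0.0619) or replicate 2 (0.169 and 0.102), and the crosslinking call without TCP replicate 3 (0.081).

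Gene classes were compared by their median changes in A549 cells on TCP, without a test of any class. Against 50 kPa, median log2 fold changes were 0.02 for 13508 protein-coding genes, -0.39 for 577 lincRNAs, -0.37 for 730 antisense genes and -0.32 for 64 sense intronic genes. They were -0.49 for 169 processed transcripts, -0.41 for 133 genes of the class TEC and -0.4 for 218 transcribed unprocessed pseudogenes. Processed pseudogenes, 342 of them, had 0.01. LincRNAs made 0.253%, 0.389% and 0.242% of counts in TCP replicates 1, 2 and 3, and 0.348% to 0.375% on 50 kPa. Of the 774 genes lower by 2-fold or more, 480 were protein coding, 77 lincRNA and 85 antisense. The strand setting of the counting is not given in the sources used here, so values for antisense genes are uncertain.

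**Figure D3:**
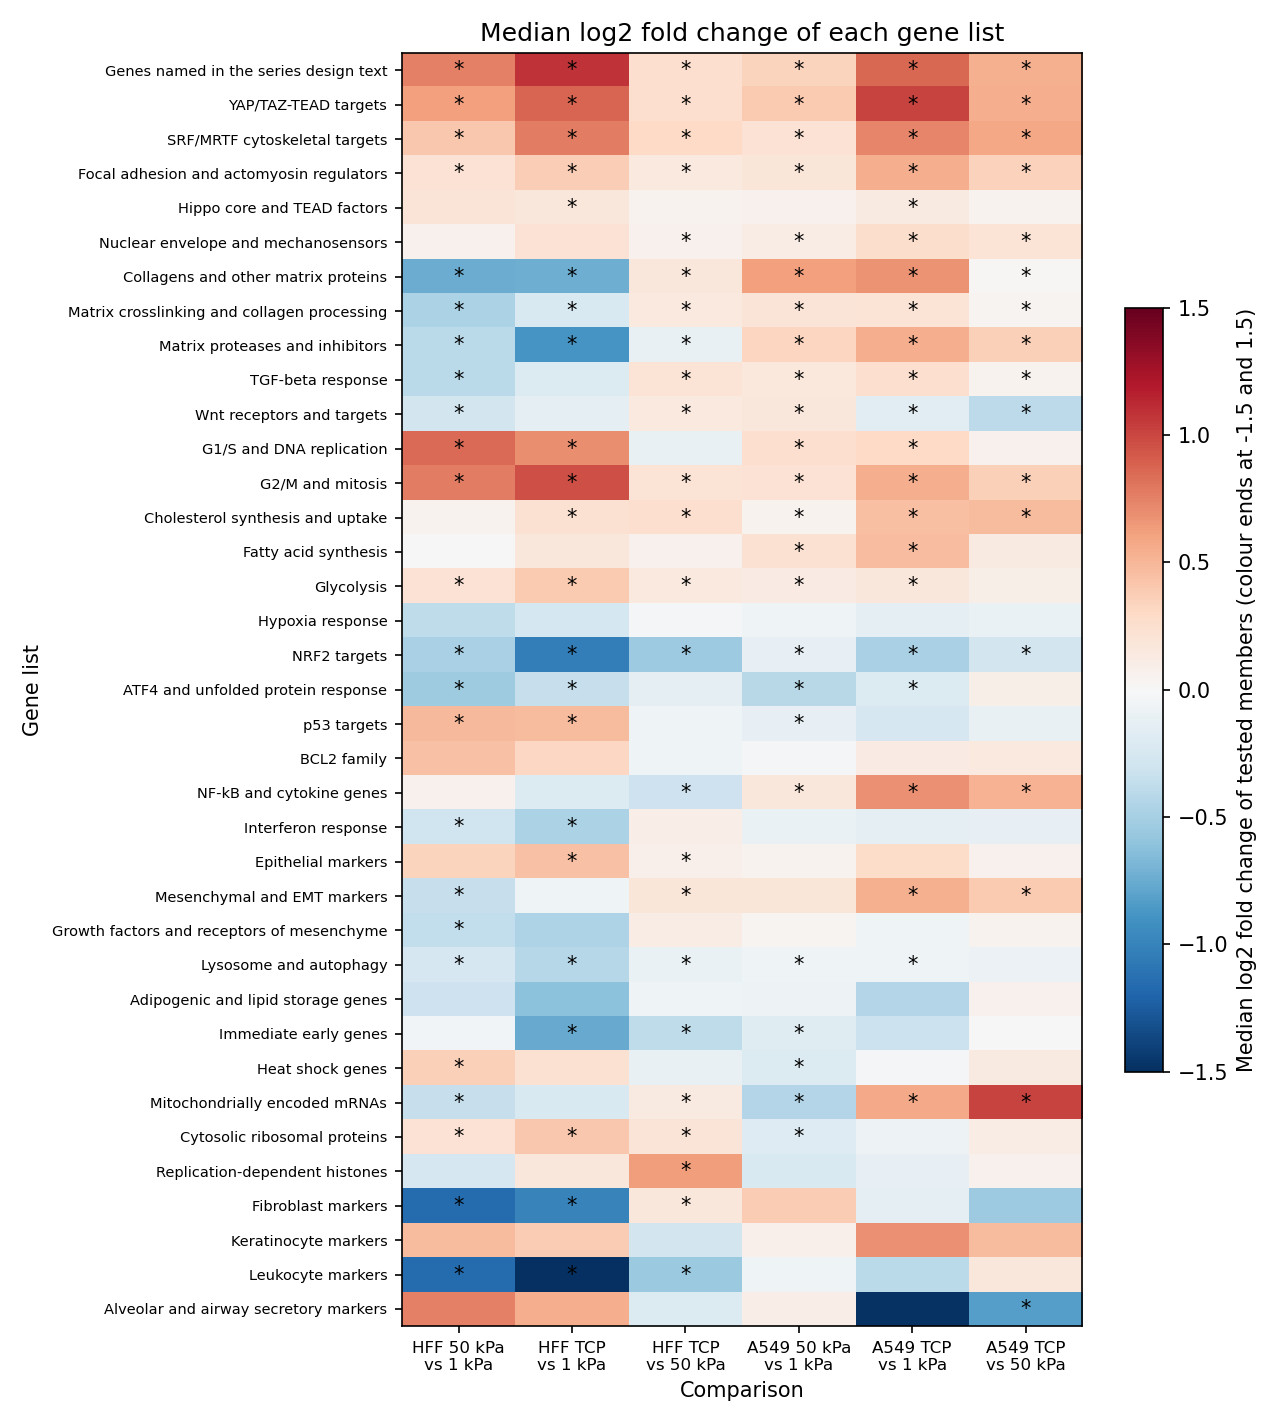
Median log2 fold change (colour) of the tested members of each gene list (y axis) in each comparison (x axis); an asterisk marks lists past an adjusted p of 0.05 in camera with the preset correlation. Collagens and other matrix proteins had -0.74 in HFF cells and 0.61 in A549 cells on 50 kPa against 1 kPa, the latter 0.37 without A549 50 kPa replicate 3.

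The response to the stiff hydrogel was set side by side between the cell types with a test of the difference itself, fitted to all 15 libraries. In 4230 of 18424 genes the change from 1 to 50 kPa differed between A549 and HFF cells, 2127 with a higher and 2103 with a lower fold change in A549 cells. BMF differed by 3.96 ± 0.25 on the log2 scale (adjusted p = 2.84e-07), CCN1 by -1.06 ± 0.15 (adjusted p = 0.000172) and PMAIP1 by -2.54 ± 0.16 (adjusted p = 2.84e-07). NPTX1, a neuronal pentraxin, moved in opposite directions, from 19.08 to 2.225 CPM in HFF cells and from 73.64 to 131.8 CPM in A549 cells (difference 3.98 ± 0.27, adjusted p = 7.91e-07). COL5A1 differed by 1.99 ± 0.23 (adjusted p = 4.53e-05). MYH9 and CCN2 were not found to differ, with 0.22 ± 0.22 (adjusted p = 0.522) and -0.33 ± 0.28 (adjusted p = 0.453). The count was 2601 without HFF 1 kPa replicate 1.

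By lists, 16 of 28 matrix genes had a higher fold change in A549 cells and 0 a lower one (23 and 0 when adjusted over the list alone), with a median difference of 1.46, which was 0.93 (adjusted p = 3.53e-09) without A549 50 kPa replicate 3. In A549 cells 24 of the 28 passed the filter on low counts. Outside that replicate, DCN and POSTN reached at most 0.029 and 0.0309 CPM in A549 cells. The median difference thus rests in part on genes near 0 in A549 cells and is no fold. G1/S genes had a lower fold change in A549 cells in 17 of 30 cases (19 when adjusted over the list alone), median -0.67, which was -0.37 (adjusted p = 4.29e-06) without HFF 50 kPa replicate 2. Heat shock genes had a lower one in 10 of 12 cases, counted either way, with HSPD1 going from 210.1 to 393.3 CPM in HFF cells and from 1089 to 1004 CPM in A549 cells. Camera gave adjusted p = 2.83e-07, 2.07e-09 and 9.33e-06 for these lists, and adjusted p = 0.374, 0.378 and 0.295 with an estimated correlation. YAP/TAZ-TEAD targets were not found to differ as a list (camera adjusted p = 0.073), with 7 of 22 lower and 2 higher in A549 cells (8 and 3 when adjusted over the list alone). Camera called 15 of 38 lists, 0 of them with an estimated correlation, and fry called 19.

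Lists that camera did not call in HFF cells on 50 kPa against 1 kPa still held single changed genes. In HFF cells Hippo genes had 8 higher and 3 lower of 18, nuclear envelope genes 4 and 4 of 15, cholesterol genes 6 and 4 of 24, fatty acid genes 2 and 2 of 11, and hypoxia genes 3 and 8 of 16. BCL2 family genes had 6 higher and 2 lower of 13, NF-kB genes 4 and 5 of 19, immediate early genes 7 and 9 of 19, epithelial markers 5 and 3 of 14, and adipogenic genes 2 and 3 of 10. Replication-dependent histones, whose reads are shared between copies, had 0 higher and 1 lower of 11, and keratinocyte markers 1 and 0 of 5. Melanocyte and endothelial markers, with 3 tested genes each, had 0 and 1 higher and 1 and 1 lower, and the alveolar list had 1 tested gene, which was higher.

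Of 14646 genes tested in both fits, 61 were called in the same direction in HFF and A549 cells on 50 kPa against 1 kPa, 33 higher and 28 lower, where independent calls would give 27.6, and 21 were called in opposite directions. Fisher's exact test over genes, two-sided, gave p = 3.38e-06 for the higher and p = 6.53e-06 for the lower genes, and genes are not independent replicates. The shared genes included CCN1, CCN2, ANKRD1 and AMOTL2 among those higher, and ASNS, PHGDH, PSAT1 and NUPR1 among those lower. The overlap was 667 genes, with 367 expected, without A549 1 kPa replicate 3, and 0 without A549 50 kPa replicate 3, where the A549 comparison called 0 genes. Across 7177 abundant genes the fold changes of the cell types had a correlation of 0.022, and 0.167 without A549 1 kPa replicate 3.

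**Figure D4:**
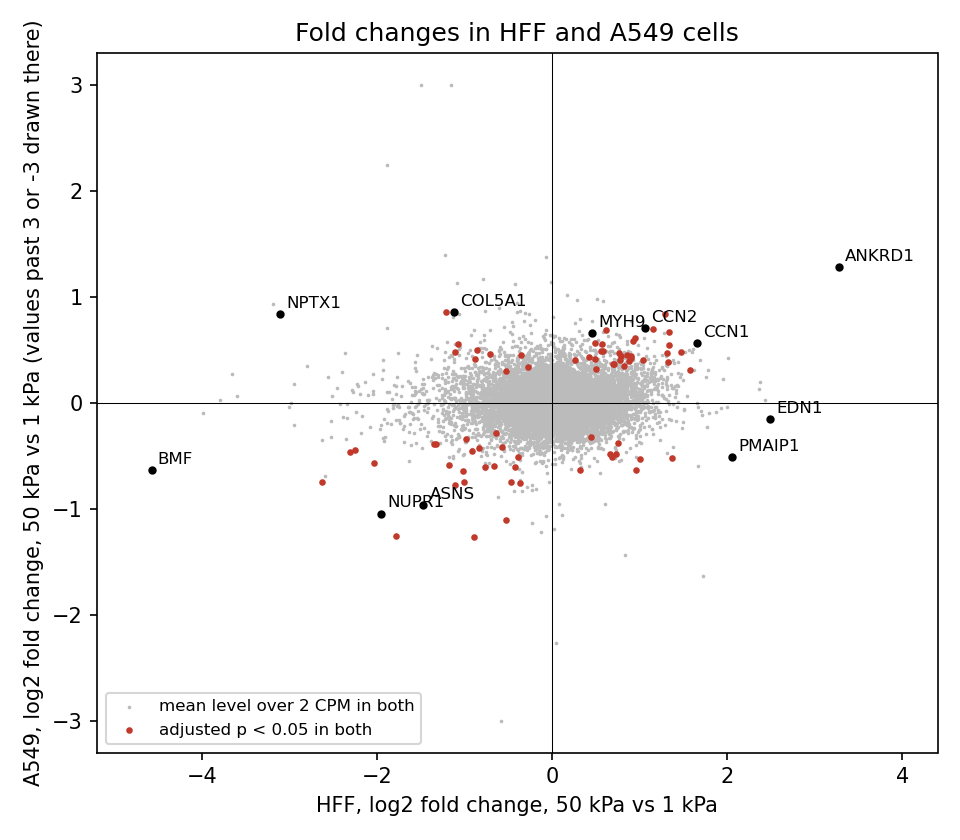
Log2 fold change on 50 kPa against 1 kPa in HFF cells (x axis) and in A549 cells (y axis, values past 3 drawn at 3); each point is a gene, and red points passed an adjusted p of 0.05 in both. ANKRD1, CCN1 and CCN2 were higher in both cell types, and NPTX1 and COL5A1 were lower in HFF cells and higher in A549 cells.

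A549 50 kPa replicate 3 held transcripts of fibroblast genes. Of 41 genes with at least 100 CPM on average in HFF cells and under 1 CPM in each of the other 8 A549 libraries, 31 were higher in this library than in those 8. COL6A3 had 31.0 CPM against at most 0.668, and COL1A2 had 26.8 CPM against at most 0.599. These 2 genes were chosen after their values were seen, as was POSTN, with 2.20 CPM against at most 0.0309. For the typical gene of the 41 the excess was 0.168% of its HFF level.

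**Figure D5:**
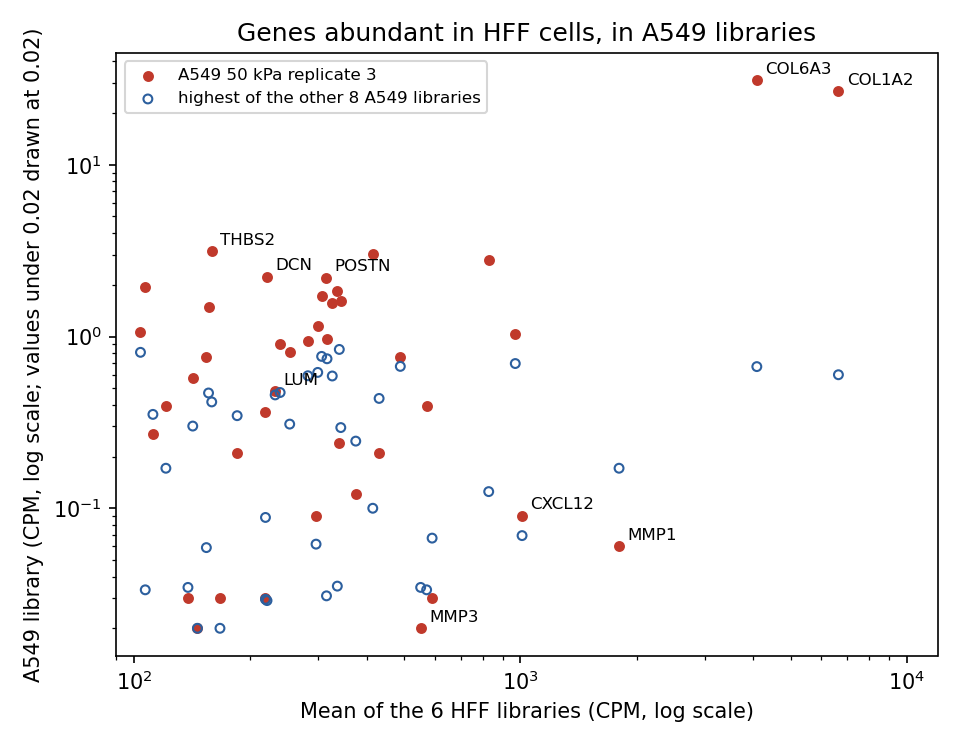
Level in A549 50 kPa replicate 3 (filled) and in the highest of the other 8 A549 libraries (open) of 41 genes abundant in HFF cells (y axis, CPM, log scale) against their mean in HFF cells (x axis, CPM, log scale). COL6A3 and COL1A2 stand out in that library at 31.0 and 26.8 CPM.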

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

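The tests of fibroblast transcripts in 1 A549 library and of histones on TCP, the leave-outs of both A549 gel libraries numbered 3, and the ratios of spread with 1 HFF library left out, were chosen only after the result was seen, and the thinning after the gene counts were seen but with its limits set before its own result. What singled out the genes and lists given first is a test of the difference itself: the change from 1 to 50 kPa in A549 cells less that in HFF cells, in a joint edgeR fit. By this test 4230 genes differed. The patterns weighed at the end of this part were picked on reading the tables instead. Of the genes named in the series description, BMF had a difference of 3.96 on the log2 scale, CCN1 -1.06, RFLNB -0.83, NF2 -0.63, RANGAP1 -0.63 and SKP2 -0.44. SKP2 was the least steady: its adjusted p of 0.0426 was 0.101 without A549 50 kPa replicate 3, 0.0753 without A549 50 kPa replicate 1, 0.0678 without A549 1 kPa replicate 2, 0.107 and 0.0612 without HFF 1 kPa replicate 1 or 2, and 0.0555 without HFF 50 kPa replicate 2.

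Among abundant genes with large differences, NPTX1 had 3.98, HR 3.95, PMAIP1 -2.54 and KLF2 -2.24, the last -1.35 without HFF 50 kPa replicate 2 and -2.02 (adjusted p = 0.066) without both A549 gel libraries numbered 3. CLDN1, with -2.19, had 0.41 CPM in HFF cells on 1 kPa and 2.36 CPM on 50 kPa. ANGPTL2 had 6.93 and CXCL12 4.61, but A549 cells held 0.00951 and 0.264 CPM of ANGPTL2 on 1 and 50 kPa and 0 and 0.0512 CPM of CXCL12, so these values rest on the count added before the logarithm and are no folds. Without A549 50 kPa replicate 3, ANGPTL2 had 4.50 (adjusted p = 0.0492) and CXCL12 3.97 (adjusted p = 0.116), and without both A549 gel libraries numbered 3 they had 4.02 (0.0787) and 3.99 (0.155). FGF1, with -3.06, had 0.145 and 0.0398 CPM in A549 cells, and -2.35 (adjusted p = 0.0517) without A549 1 kPa replicate 2.

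By lists, the median difference was 1.46 for collagens and other matrix proteins, 0.82 for matrix crosslinking, 0.91 for matrix proteases, 0.65 for TGF-beta response, 0.34 for Wnt, 0.54 for mesenchymal markers, 0.43 for mesenchymal growth factors, 0.29 for lysosome and autophagy and 2.84 for fibroblast markers. It was -0.67 for G1/S, -0.59 for G2/M, -0.58 for p53 targets, -0.57 for heat shock genes and -0.37 for ribosomal proteins, and 0.35 for NRF2 targets. Camera called these 15 lists with the preset correlation and 0 of them with the estimated one, and fry called 19 lists. Without A549 50 kPa replicate 3, the matrix list had 0.93, matrix proteases 0.43 and fibroblast markers 0.69. In A549 cells 24 of 28 matrix genes, 14 of 19 proteases and 7 of 10 fibroblast markers passed the filter on low counts. Among the markers, COL1A2, DCN and LUM had at most 0.599, 0.029 and 0.457 CPM in the other A549 libraries. The medians of these lists thus rest in part on genes near 0 in A549 cells and are no folds. Without HFF 50 kPa replicate 2, G2/M had -0.09 (adjusted p = 0.327), NRF2 0.01 (0.475), growth factors 0.27 (0.162) and G1/S -0.37. Growth factors had 0.38 (adjusted p = 0.0717) without both A549 gel libraries numbered 3. Without HFF 50 kPa replicate 1, p53 had -0.13 (adjusted p = 0.113). Without A549 1 kPa replicate 3, Wnt had 0.20 and ribosomal proteins -0.19. The lysosome call was lost without HFF 1 kPa replicate 2 (adjusted p = 0.077) or A549 1 kPa replicate 2 (0.0676).

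More genes changed in HFF than in A549 cells on 50 kPa against 1 kPa, 6612 against 141. Greater depth of the HFF libraries is argued against by thinning their counts to the depth of the A549 libraries, which left 6175 called genes. Larger fold changes in the fibroblasts are in line with a spread of log2 fold changes, less error variance, 3.02 times that of A549 cells, or 3.57 times without A549 1 kPa replicate 3, and 2.9 to 4.04 times when 1 HFF library was left out too or instead. How much of the gap wider spread from A549 1 kPa replicate 3 makes cannot be told apart from the smaller changes: without it A549 cells had 1849 called genes, fewer than 6612, and the fit had 1 library less. Seeding numbers differed between 1 and 50 kPa in both cell types and their effect could not be tested.

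Fibroblast transcripts stood out in A549 50 kPa replicate 3. A response to the 50 kPa hydrogel is argued against, since 0% of 41 genes, abundant in HFF cells and under 1 CPM in the 6 A549 libraries on 1 kPa and TCP, had both other 50 kPa libraries above those 6. The HFF cultures of this series as the source are argued against by the uneven excess, though it correlated with HFF levels on 1 kPa at 0.596: of 13 genes that the median share would give 20 reads or more, 38.5% lay within 4 times of that share, and MMP1 had 2 reads where 97.8 would be due. Fibroblast RNA or cells mixed into this library remain open, as 75.6% of the 41 genes lay above all other A549 libraries, but the genes had been noticed in that library before the test. The matrix and fibroblast lists in A549 50 kPa comparisons may carry RNA of other cells.

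More genes were lower than higher at 2-fold or more in A549 cells on TCP against 50 kPa, 774 against 132. Replication-dependent histones were not lower on TCP, with a median log2 fold change of 0.07. This cannot settle whether RNA without poly(A) tails was less on TCP, as histone reads are shared between copies. These histones also depend on DNA replication, and G1/S genes summed to 4431 to 4495 CPM on TCP against 4247 to 4313 CPM on 50 kPa. Less unspliced or nuclear RNA on TCP cannot be told apart from regulation of single genes: sense intronic genes had a median of -0.32, and the reads were not assigned to introns here.

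For the A549 comparisons, the 6 libraries of each allow 10 splits, too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many genes as observed: 141 for 50 kPa against 1 kPa, 5776 for TCP against 1 kPa and 3605 for TCP against 50 kPa, with 0 genes as the highest of the other splits. Each other split mixes libraries of both groups, so a real difference widens its spread and keeps calls near 0. The gap between the real split and the others is therefore no further support for the counts.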

How the results depend on the processing

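The whole-number counts of the authors' deposited table, the crossed pairing, the thinning, the leave-out of both A549 gel libraries numbered 3 and the leave-outs for the overlap were chosen only after seeing the data, the thinning with its limits set before its own result. Of alternatives for counts, 77 stayed within 1.5 times and 55 moved further. For named genes 11514 alternatives kept the side of the threshold, 794 lost the call, 44 gained one and 1 turned direction. For lists these numbers were 2514, 262, 94 and 3. Turns of direction were counted only where the gene or list was called in the main test or the alternative. In the order HFF 50 kPa against 1 kPa, HFF TCP against 1 kPa, HFF TCP against 50 kPa, the same in A549 cells, and the difference between cell types, an adjusted p under 0.01 gave 3485, 4390, 8, 5, 3438, 1800 and 2250 genes, and a 2-fold limit gave 1682, 2205, 24, 12, 1413, 906 and 1379, lower by construction. The overlap of calls between cell types, 61 genes, was 2 and 3 under these limits. For HFF TCP against 50 kPa, 76 genes became 757 with DESeq2, 38 with limma-voom, 4 with limma-trend on TPM, 1384 without a filter, 5 with only the 2 groups in the fit and 167 with the counts of the deposited table. For A549 50 kPa against 1 kPa, 141 genes became 869 with DESeq2, 44 with limma-trend, 221 with a mean of at least 5 CPM, and 0 with only the 2 groups in the edgeR fit, where limma-voom with all groups gave 135 and 2983 genes had an unadjusted p under 0.05. For A549 TCP against 50 kPa, 3605 became 7155 with only the 2 groups. The overlap was 325 with DESeq2. Across genes, residuals of libraries with the same number correlated at -0.103 between HFF 1 and 50 kPa, at -0.025 and -0.027 between these and HFF TCP, and at 0.025 to 0.134 between A549 groups, where each library correlated best with its own number, a hint from the data and not from the design. A block for replicate number gave 10 genes for HFF TCP against 50 kPa and 76 for A549 50 kPa against 1 kPa, and 5841 for HFF 50 kPa against 1 kPa, 5777 of them shared with the 6612. As the first value was negative, the numbers on 50 kPa were exchanged, and this crossed pairing gave 6579 genes there, 6284 of them shared. It was chosen from the same data and cannot establish that numbers were crossed. With 2 libraries per group such a sign can come from any difference between them. All HFF values were negative, and exchanging the numbers of 1 group cannot make them all positive. Without both A549 gel libraries numbered 3, A549 50 kPa against 1 kPa had 1027 genes, TCP against 50 kPa 6375 and the overlap 402. With 1 library left out, counts ranged from 2838 to 9287 for HFF 50 kPa against 1 kPa, 3646 to 4218 for HFF TCP against 1 kPa, 3 to 3552 for HFF TCP against 50 kPa, 0 to 1849 for A549 50 kPa against 1 kPa, 4172 to 8009 for A549 TCP against 1 kPa, 2221 to 2533 for A549 TCP against 50 kPa, and 2601 to 5414 for the difference. For the overlap only 2 libraries were left out in turn: it was 0 without A549 50 kPa replicate 3 and 667 without A549 1 kPa replicate 3. List medians for HFF TCP against 50 kPa ranged over leave-outs from -0.33 to 0.16 for G1/S, -0.17 to 0.76 for G2/M and -0.32 to 0.41 for p53 targets, with G2/M and p53 turning direction without HFF 50 kPa replicate 1 and G1/S without HFF 50 kPa replicate 2. The difference of SKP2, -0.44, was 0.09 (adjusted p = 0.855) with limma-trend on TPM. Apart from limits and fewer samples, the cause was not tested. Depth limited calls little in HFF cells, where 6175 genes were called after thinning, 5901 of them shared.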

Other observations

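Some genes called in both cell types on the stiff hydrogel are given here. The choice to look at single genes in this part was made after the calls were seen. Among the 61 genes called in the same direction in HFF and A549 cells, AMOTL2, an angiomotin that binds YAP, had log2 fold changes of 1.15 and 0.69, and PHGDH, of serine synthesis, had -0.77 and -0.61. ANKRD1 had 3.27 in HFF cells and 1.28 in A549 cells, and NUPR1 had -1.96 and -1.05. The A549 calls of these genes were lost without A549 50 kPa replicate 2 or 3, where the edgeR test called 0 genes, while DESeq2 with all libraries called 869 and 2983 had an unadjusted p under 0.05.

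In A549 cells, 7 genes with little or no signal in HFF cells reached 2 CPM or more in 1 kPa replicate 3. These genes stayed well under that level in every other A549 library. There was 1 such gene for 50 kPa replicate 3 and 0 for the other 7 libraries.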
